A study of Homo sapiens with 12 samples.

How the data were processed

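The series measured N6-methyladenosine (m6A), the methyl mark on adenosines of messenger RNA, by m6A-seq. In this assay poly(A)-selected RNA is fragmented and pulled down with an anti-m6A antibody, and the pulled-down fragments (IP) are sequenced beside unselected fragments (input). The cells were HEK293A-TOA, a human embryonic kidney cell line grown in tetracycline-free serum. They were transfected with 30 nM of a control siRNA (siCtrl) or an siRNA against METTL16 (siMETTL16) and collected after 96 hours, per the labels' protocols. The 12 libraries comprise 3 IP and 3 input libraries per siRNA, which the series design text calls biological replicates.

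The submitters' processing notes list the aligner BWA (version 0.7.9a-r786), StringTie (version 1.1.2) and the build hg38, with no role given for any of them. The deposited expression table has 6 columns of gene-level FPKM, per the name of the table. Each column is headed by a replicate number and the letter A or B, and no source used here ties a letter to an siRNA. Letters were not assigned from column order or from the level of the targeted gene, so these 6 columns were not used in any step. The planned limma comparison of siMETTL16 with siCtrl inputs, the check of the METTL16 knockdown, the gene set tests on expression and the comparison of peaks with transcript levels were therefore not run.

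The authors deposited 1 peak list, which the labels of the 6 m6A-IP libraries name. Per the file headers it gives each peak a chromosome, start, stop, strand, Ensembl gene identifier and gene name. The deposited score column is 0 for all 2715 peaks and holds no measurement. The peak caller, its threshold, the use of the inputs, the pooling of replicates and the condition or direction that a listed peak stands for are not given in the sources used here. The list carries no value per library, no fold change and no p-value, so the planned test of changed peaks was not run. Library depth is unknown, and no limit on detection could be set from it. A gene without a peak in the list may be unmethylated, too weakly expressed, below the threshold or outside the selection that the list represents.

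Peak widths (stop minus start) are multiples of 50 bases for 2643 peaks, so the coordinates were read as 0-based and half-open. Positions are printed 1-based, on hg38. Gene spans and gene types came from a RefSeq gene table of the same build (GRCh38.p14), which holds 1 span per gene and no exons. Of the 1528 gene identifiers, 1473 (96.4%) were matched to it, to 1472 genes, through the current Ensembl symbol, the deposited name or a unique synonym, with the chromosome required to agree. Introns, exons and UTRs were not annotated here, and no sequence was searched for methylation motifs, because no genome or exon annotation was used. The planned assignment of peaks to parts of transcripts was replaced by the position of the peak centre along the gene span, from 0% at the 5' end to 100% at the 3' end. Of the 2638 peaks in matched genes, 2551 had their centre in the span of their gene.

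The gene lists were fixed before the data were examined. List symbols were matched to RefSeq symbols or unique synonyms. The share of each list's protein-coding genes with at least 1 peak was compared with all other protein-coding genes of chromosomes 1 to 22 and X that also have an Ensembl symbol (19110 genes in all) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 22 lists of at least 5 such genes. Of the matched protein-coding peak genes, 9 fell outside this background. Since expression was not used, the background includes genes that these cells do not express, and a list of expressed genes can exceed it for that reason alone. Intervals on shares are exact 95% Clopper-Pearson intervals. For a share of 0, the limit given is 3 genes of the list's total. This is an approximate one-sided 95% bound, lower than the upper end of the exact two-sided interval. Intervals and limits cover counting error only. The share of peaks in the last 10% of the span was compared with uniform placement in 10000 simulated lists, two-sided. The gaps between neighbouring peaks were compared with 1000 random placements of the same peaks in the spans of their genes, one-sided. These list, position and gap tests, and the tests of the closing section, replaced the planned ones once the content of the list was known. The background was also changed after first results had been seen. It first held all 19974 RefSeq protein-coding genes, including genes that have no Ensembl symbol and so could not match the list, and its results are given as an alternative.

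The named-gene rule, written before the data were examined, covers METTL16 and MAT2A. Its parts that need fold changes could not be applied. The other genes named are members of the fixed lists with a peak, listed members without one, genes with 8 or more peaks, the widest peaks and examples from symbol families, and these were chosen after the list was seen. The peaks of 1 list member are not reported here. Alternatives joined neighbouring peaks, kept only peaks of at least 150 bases, required 2 peaks per gene, kept only peaks in the span of 1 protein-coding gene, or changed the background, and these were chosen after the list was seen.

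The tests were also run on simulated data with known answers. Lists of 36 genes with a simulated peak share of 28% were called in 81.2% of cases, and unchanged lists in 0.4%, on the 19110 background genes. Several lists were raised together in each simulated round, so the rate for a single raised list may be lower. The test of the spread over chromosomes permutes blocks of 5000000 bases, 10000 times for the deposited list and fewer times for each simulated list. In it, lists that depend on gene density only were called in 3% of cases on the same genes, and lists with 1.6 times the share on 5 chromosomes in 100%. These simulated lists draw each gene independently, without clustering of neighbouring peak genes, so the second rate does not carry over to a list with such clustering. Uniform lists of 2500 peaks were called in 3% of cases by the position test. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.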

Results

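The m6A peak list of HEK293A-TOA cells held 2715 peaks in 1528 genes on 23 chromosomes. Of these peaks, 1346 lay on the plus strand and 1369 on the minus strand, and together they covered 457734 bases. Their median width was 150 bases (quartiles 100 and 200, range 69 to 1000), and 1187 peaks (43.7%) were exactly 100 bases wide. Of the 1472 matched genes, 1410 (95.8%) were protein-coding, 39 were long noncoding RNAs, 22 were pseudogenes and 1 was an antisense RNA. The labels name this list for the 3 siCtrl and 3 siMETTL16 IP libraries alike, and it carries no value for either condition. It therefore gives positions only, with no replicate error, and no siMETTL16 against siCtrl difference was estimated. The sequencing depth behind the peaks is unknown. Whether the list holds all m6A peaks found or only a selection, such as peaks that differ between the siRNAs, is also unknown. The positions, shares and missing peaks below therefore describe the list, and not necessarily all m6A of these cells.

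The series title links METTL16, the methyltransferase of U6 snRNA, to SAM synthetase, so the SAM synthetase gene was examined first. MAT2A (ENSG00000168906), which encodes the SAM synthetase of most non-liver tissues, carried 2 peaks, both toward the 3' end of the gene. MAT2A spans bases 85539168 to 85545281 of chromosome 2 on the plus strand. The upstream peak covered bases 85543666 to 85543965 (300 bases), with its centre at 76% of the gene span. The downstream peak covered bases 85544566 to 85545265 (700 bases), with its centre at 94% of the span, and it ended 16 bases before the annotated 3' end. The peaks were 600 bases apart and together took up 16.4% of the span. The downstream peak ranked 7 of 2715 by width, and the upstream peak ranked 187 with ties. No peak was assigned to METTL16 itself (0 peaks in the list).

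**Figure D1:**
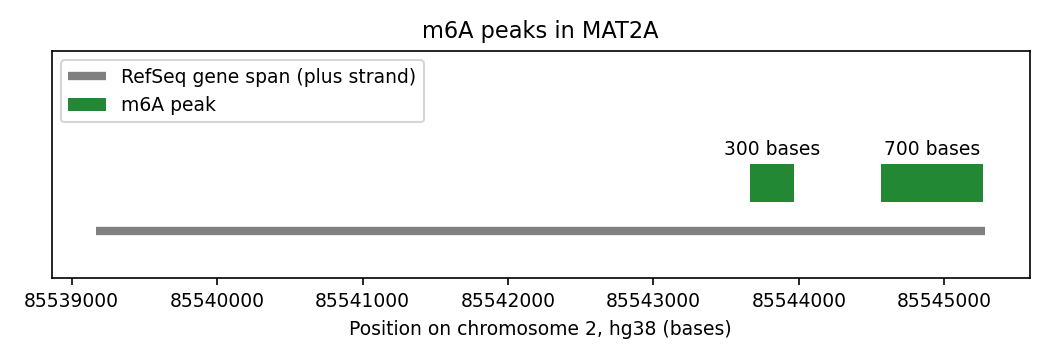
The m6A peaks in MAT2A along chromosome 2 (hg38, x axis in bases): the grey line is the RefSeq gene span and the green boxes are the peaks, with their widths. The 700-base peak ends 16 bases before the 3' end, and the 300-base peak lies 600 bases upstream of it.

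Beyond MAT2A, genes of the methionine cycle and SAM metabolism list with peaks included MTR (1 peak), the methionine synthase, PEMT (3 peaks) and GAMT (1 peak), which use SAM to make phosphatidylcholine and creatine, and MTAP (1 peak), the methylthioadenosine phosphorylase of methionine salvage. In all, 6 of 25 members (24.0%, interval 9.36 to 45.1%) carried a peak, against 7.31% of other protein-coding genes. This share did not pass the test after adjustment (odds ratio 4.0, Fisher's exact test, adjusted p = 0.0892). MAT2B, the regulatory partner of MAT2A, and AHCY, the hydrolase that clears S-adenosylhomocysteine, had no listed peak.

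The SAM-using histone, protein and DNA methyltransferases were the only list that passed the test after adjustment. Their share was near the 24.0% of the methionine and SAM list, and the lists were not compared with each other. A peak lay in 10 of 36 members (27.8%, interval 14.2 to 45.2%), against 7.29% of other protein-coding genes (odds ratio 4.89, Fisher's exact test, adjusted p = 0.00416 over 22 lists). The comparison genes include ones that these cells may not express, since expression was not used. DNMT1, the maintenance DNA methyltransferase, carried 5 peaks with 650 bases in all. PRMT2, a protein arginine methyltransferase, carried 3 peaks with 1150 bases in all, including 1 of 650 bases. KMT2B, a histone H3 lysine methyltransferase, carried 2 peaks. The others, each with 1 peak, were EZH2, the catalytic subunit of a Polycomb complex, SUV39H1, DOT1L, NSD2, SETD1A, SETD7 and KMT2C, all of them lysine methyltransferases. With genes required to hold at least 2 peaks, DNMT1, PRMT2 and KMT2B were left and the list did not pass (odds ratio 3.10, Fisher's exact test, adjusted p = 0.734, against 0.00266 to 0.028 under the other alternatives).

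The m6A machinery and the splicing lists did not pass the test. Among m6A writers, erasers and readers, 3 of 24 genes (12.5%, interval 2.66 to 32.4%, Fisher's exact test, adjusted p = 0.984) carried a peak. These were WTAP, a regulatory subunit of the METTL3-METTL14 writer, RBM15B, an adaptor of that writer, and PCIF1, the methyltransferase of cap-adjacent adenosines, each with 1 peak. METTL3, METTL14, FTO, ALKBH5 and the YTH-domain readers had none in the list. Among U6 and tri-snRNP proteins, 3 of 30 genes had peaks (10.0%, interval 2.11 to 26.5%), namely CD2BP2 (3 peaks), PRPF6 (1 peak) and LARP7 (1 peak). Among SR proteins and CLK kinases, 4 of 30 genes had peaks (13.3%, interval 3.76 to 30.7%), namely SRSF9, SRSF11, SRSF12 and SRRM2. The SRSF9 peak was 400 bases wide, and the centre of the SRRM2 peak lay outside the annotated span. Each of these lists had an adjusted p of 0.984 by Fisher's exact test.

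In the remaining metabolic, stress and cell cycle lists, from 1 to 5 genes carried a peak, and none of these lists passed the test (Fisher's exact test, adjusted p from 0.984 to 1). In the cholesterol and SREBP list 4 of 33 genes had peaks, among them FASN, the fatty acid synthase, with 5 peaks, and SREBF2, a sterol-responsive transcription factor, with 1. In the S phase list 5 of 39 genes had peaks, including FEN1, the flap endonuclease, with 3. For the nonsense-mediated decay list the count was 2 of 19, including the helicase UPF1 with 3 peaks. The ATF4 and amino acid response list gave 2 of 45, which were SLC7A5 (2 peaks) and ATF3 (1 peak). The counts were 1 of 26 for nuclear RNA decay, 1 of 16 for polyamine genes, 2 of 24 for the unfolded protein response, 2 of 26 for p53 targets, 2 of 26 for immediate early genes, 2 of 33 for mitotic genes and 1 of 37 for interferon-stimulated genes. Ribosomal protein genes gave 5 of 79 (6.33%, interval 2.09 to 14.2%), and the peak assigned to 1 of them, RPL36, lay outside its annotated span.

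Lists of other cell types or RNA classes held few peak genes, and none passed the test. Epithelial and leukocyte markers each had a peak in 0 of 16 genes (3-gene limit 18.8%, exact interval up to 20.6%). Neuronal markers had a peak in 0 of 18 (3-gene limit 16.7%, exact interval up to 18.5%). Fibroblast markers had 1 of 19, COL5A1. The adjusted p was 1 for the fibroblast list and 0.984 for the others by Fisher's exact test. Replication-dependent histone genes, whose mRNAs lack poly(A) tails, had 0 of 50 (3-gene limit 6%, exact interval up to 7.11%, Fisher's exact test, adjusted p = 0.367). None of the 14 mitochondrially encoded genes matched carried a peak. Of the 24 noncoding genes matched in the snoRNA host list, 2 carried peaks, SNHG29 with 3 and SNHG5 with 1, with the median peak centre of each outside the annotated span.

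**Figure D2:**
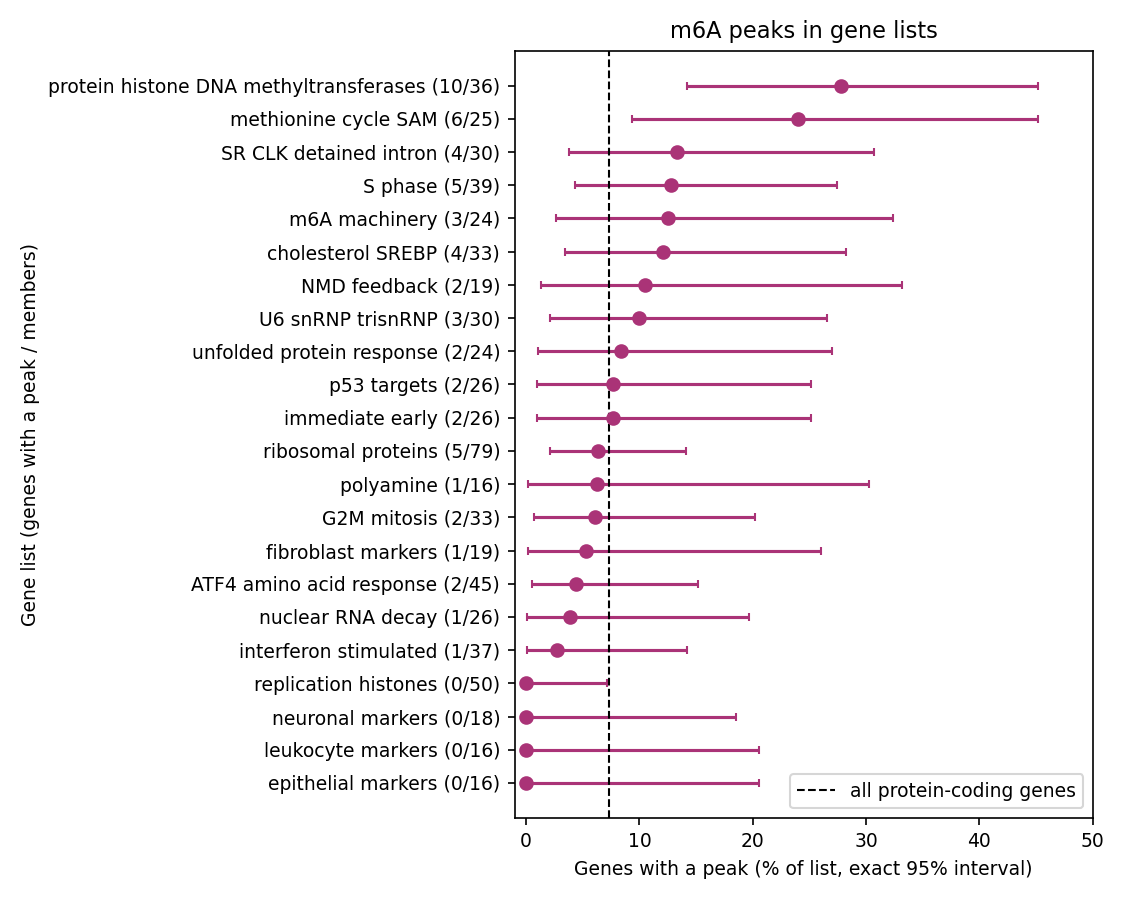
The percentage of genes with at least 1 m6A peak in each gene list (points, with exact 95% intervals), with the share in all 19110 protein-coding genes as a dashed line. The methyltransferase list lies at 27.8%, and its interval of 14.2 to 45.2% excludes the 7.33% of all genes, as do those of the methionine and SAM list (9.36 to 45.1%) and, on the low side, of the replication histones (0 to 7.11%), neither of which passed after adjustment.

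Along the gene span, peaks lay toward the 3' end. Of 2551 peaks, 674 (26.4%, interval 24.7 to 28.2%) had their centre in the last 10% of the span and 128 (5.02%, interval 4.20 to 5.94%) in the first 10%. The share in the last 10% exceeded uniform placement (two-sided simulated binomial test, p = 0.0001, the smallest that 10000 lists can give). Peaks of the same gene are not independent, and among the 870 placed genes with 1 peak the share was 33.1% (the same binomial test, p = 0.0001). The median centre lay at 74.8% of the span, and 1878 peaks (73.6%) lay past its midpoint. Averaged per gene, the mean centre position was 68.7% ± 26.5 (SD over 1426 genes). The median distance to the annotated 3' end was 4346 bases (quartiles 2050 and 9725). The centre lay within 1000 bases of the 3' end for 262 peaks (10.3%, interval 9.12 to 11.5%) and within 1000 bases of the 5' end for 127 (4.98%). Genes with several peaks had on average 24.6% of theirs in the last 10%, less than the single-peak genes (556 genes, difference -8.47 percentage points, two-sided permutation p = 0.0003). This difference was not adjusted for span. Genes with several peaks also had shorter spans, and the share was 31.4% among peaks in spans of at least 10000 bases. Uniform placement takes no account of introns, which were not annotated here.

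**Figure D3:**
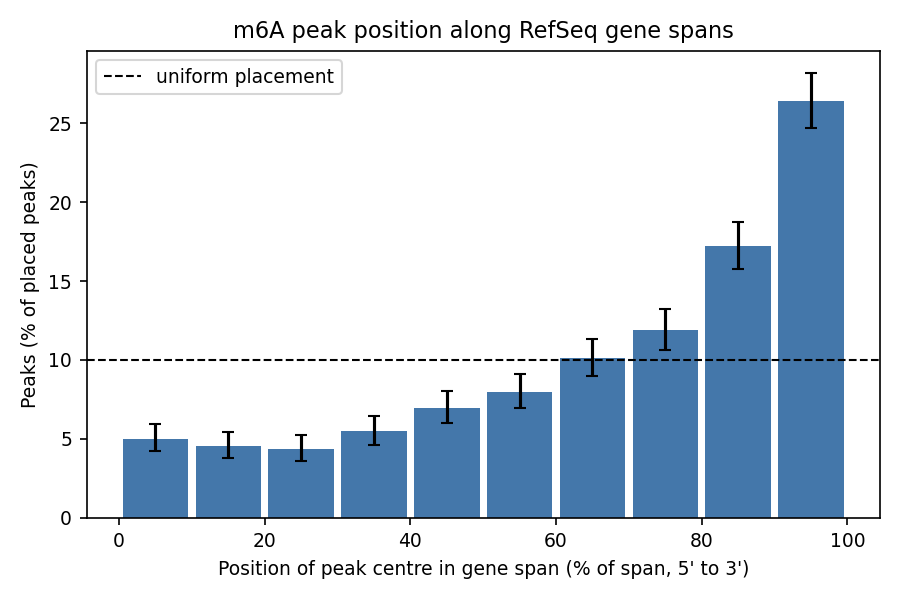
The position of 2551 m6A peak centres along RefSeq gene spans, from 5' to 3' in steps of 10% (bars, with exact 95% intervals), with uniform placement as a dashed line. The share of peaks is 5.02% in the first step and 26.4% in the last.

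Many genes carried more than 1 peak. Of the 1528 genes, 947 had 1 peak, 306 had 2 and 74 had 5 or more, and the 581 genes with several peaks (38.0%) held 1768 of the 2715 peaks. WDR90 on chromosome 16 had 24 peaks between bases 650262 and 667611, with 4700 bases in all, in a gene span of 18852 bases. RTEL1, a helicase that acts at telomeres, had 13 peaks, MGAT4B, a Golgi glycosyltransferase, had 12, and TONSL, a replication fork repair factor, had 11. The RTEL1 locus also holds an annotated readthrough gene, so the assignment of its peaks is uncertain. CLCN7, a lysosomal chloride transporter, DNAH1, an axonemal dynein heavy chain, and PIEZO1, a mechanically gated channel, had 10 each. The other 8 genes with 8 or more peaks were LRRC45, PKD1, ANKRD13D, MRPL37, PKN3, PLXNA1, TRMT44 and VPS9D1.

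Peaks of the same gene lay closer together than under uniform placement. In 544 genes with at least 2 placed peaks, 731 of 1125 neighbouring pairs (65.0%) were at most 1000 bases apart, against a mean of 28.8% and a highest value of 32.4% in 1000 random placements (one-sided simulated p = 0.001, the smallest these placements can give, n = 544 genes). The median gap was 550 bases (quartiles 182 and 1750). These placements ignore exons, within which fragments of spliced RNA would fall. They also ignore the lean of peaks toward the 3' end, which alone brings peaks of a gene closer. Clustering beyond that lean was not tested.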

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

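The alternatives reported here were chosen after the peak list was seen, except the count of peaks by any overlap, which was applied to the gene span in place of transcript parts. No paired analysis was possible because the expression columns carry no condition name and the peak list has no values per library. For the same reasons other pseudocounts, filters, normalizations, variance models and gene set tests, left-out replicates and stricter peak thresholds were not run, nor were other motif windows, for want of a genome. Keeping only peaks at least 150 bases wide left 1502 peaks and 285 genes with several peaks. It reduced the chromosomes with a lower share of peak genes from 9 to 5. Chromosome counts here come from Fisher's exact tests that treat genes as independent. Requiring at least 2 peaks per gene left 0 gene lists past the threshold by Fisher's exact test (1 list at an unadjusted p under 0.05), and the methyltransferase odds ratio fell to 3.10, with 3 members left to count. The other 27 of 32 alternative values kept their direction and their side of the threshold, or stayed within 1.5 times the reported count. The share of peaks in the last 10% of the span ranged from 25.3% to 33.1% over its 4 alternatives. The methyltransferase odds ratio lay between 4.91 and 5.19 under the 4 alternatives that kept genes with 1 peak. With all 19974 RefSeq protein-coding genes as background, as first run, it was 5.09 (adjusted p = 0.00305 by Fisher's exact test), and 10 chromosomes were lower rather than 9. Joining peaks at most 500 bases apart left 2130 peaks and 405 genes with several peaks. The unknown depth and the unknown threshold of the list limit what the absence of a peak shows.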

Other observations

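The tests of gene families and chromosome shares were chosen after the peak list was seen, and the tests that weigh explanations were chosen after the patterns were seen. What each explanation predicts was written before its test was first run, on the wider background of 19974 genes, except for the chromosome pattern, whose block permutation was chosen after related odds ratios had been seen. Among 96 families of protein-coding genes that share a symbol stem (at least 20 members each), olfactory receptors (stem OR) had a peak in 0 of 382 genes. They passed the test (3-gene limit 0.785%, exact interval up to 0.961%, Fisher's exact test, adjusted p = 4e-11). Other families did not pass, the nearest being the keratin-associated proteins (stem KRTAP) at 0 of 94 (3-gene limit 3.19%, exact interval up to 3.85%, Fisher's exact test, adjusted p = 0.0578). Expression was not used, so a lack of transcripts in these cells could alone give 0 peaks in either family. The test therefore says nothing on their methylation. The highest shares among the next families by p were CDK-stem genes at 7 of 28 (25%), including the transcriptional kinases CDK9 and CDK12, adaptor complex genes (stem AP) at 7 of 29 (24.1%), and Mediator subunits (stem MED) at 7 of 30 (23.3%), including MED1 and MED12. CEP-stem genes gave 8 of 38 (21.1%) and WDR-stem genes 11 of 58 (19.0%). Each of these had an adjusted p of 0.0756 by Fisher's exact test.

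The widest peaks lay in RECQL4, a DNA helicase (1000 bases, chromosome 8, bases 144512139 to 144513138), TMEM94 (950 bases), PCSK4, a proprotein convertase (900 bases), and SLC6A8, the creatine transporter (900 bases). PCSK4, RECQL4 and TMEM94 had their peak centres at 74.6%, 79.4% and 83.4% of the gene span, whereas the SLC6A8 peak lay at 20.5%.

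Peak genes were unevenly spread over chromosomes. On chromosomes 9, 16, 17, 19 and 22, 554 of 4489 protein-coding genes (12.3%) had a peak, against 5.79% on the others. Each of the 5 passed Fisher's exact test after adjustment over 23 chromosomes. Those tests treat genes as independent although neighbouring peak genes are clustered, so their adjusted p-values are likely too small. Chromosome 16 was highest at 134 of 811 genes (16.5%, interval 14 to 19.3%, adjusted p = 5.12e-18), and chromosome 18 lowest at 6 of 256 (2.34%, interval 0.865 to 5.03%, adjusted p = 0.00275). Local gene density may account for this. Over all 23 chromosomes, the spread of peak genes exceeded that of permuted blocks of neighbouring genes (5000000 bases each, one-sided permutation p = 0.0004). Around the numbers expected from deciles of the genes within 500000 bases it no longer did (permutation p = 0.135). The odds ratio of the 5 chromosomes against the others fell from 2.29 (interval 2.05 to 2.56) to 1.63 (interval 1.44 to 1.84) within these deciles, with intervals that ignore both the choice of these chromosomes by their shares and the clustering of peak genes. Simulated lists with 1.6 times the share on 5 chromosomes were called in 100% of cases, but without such clustering, so a difference beyond density was neither shown nor excluded. With deciles of gene length, taken as the gene span, the spread still exceeded that of permuted blocks (permutation p = 0.0019). This argues against span length as the whole cause. Base composition, exon number, transcript length without introns and transcript abundance were not tested and stay open.

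That several peaks fall in 1 gene may come from the calling windows or from the length of the gene span. The values argue against longer spans as the cause. Against the windows they argue only in part, for gaps of at most 100 bases. Joining peaks at most 100 bases apart left a single peak in 46 of the 581 genes (7.92%, interval 5.85 to 10.4%), and joining those at most 500 bases apart left 1 peak in 176 (30.3%, interval 26.6 to 34.2%). Both are under the 50% that was set, for joining at 100 bases, as the mark of divided broad regions. The share at 100 bases argues against windows with gaps of at most 100 bases as the main cause, though part of the pattern may arise in this way. A gene counts here only if all its peaks join into 1. Counted by pairs, 49.7% of neighbouring placed peaks were at most 500 bases apart, so the joining does not decide on gaps of that length. Pieces of 1 region separated by a longer intron would not be joined, so the joining cannot decide on such regions. Genes with several peaks had shorter spans than genes with 1 peak (median 19661 against 25964 bases, ratio 0.757, interval 0.660 to 0.873, permutation p = 0.0008). These spans include introns. Transcript length without introns was not measured and stays open. Whether the repeated peaks lie in retained introns, a hypothesis that the series title raises, stays open, since exons were not annotated here.

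The excess of peaks in methyltransferase genes may reflect properties of these genes other than their function. Random lists matched on gene length held 2.61 peak genes on average, against 10 observed (one-sided simulated p = 0.0001, the smallest that 10000 lists can give, n = 36 genes), and lists matched on local gene density held 3.09 (one-sided simulated p = 0.0002, n = 36 genes). These values argue against the length of the gene span or local density alone as the whole cause. The list was taken up because it passed on these same peaks, and the simulated p-values are not adjusted for that choice. Transcript length without introns was not matched and stays open. With only members of the fixed lists as background the odds ratio was 5.01. Expression in these cells was not matched and stays open, as does the direction of any change under METTL16 knockdown.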
